A study of Arabidopsis thaliana with 8 samples.

How the data were processed

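RNA of whole seedlings of wild type and laterne was compared on 8 two-colour Agilent arrays of design 015059. Per the labels, seedlings were collected on the 6th day, after 2 days in the cold at 8 °C and 4 days of growth at 18 °C, and 900 ng of RNA with an integrity number above 8 was used. There were 4 biological replicates, each hybridised to 2 arrays with the dyes exchanged. Per the file headers, the scans were read with Agilent Feature Extraction 10.7.3.1, which gave mean spot intensity and median local background intensity per channel on a linear scale, processed intensity after background subtraction, detrending and dye normalization, and the log10 ratio of processed red over green. The deposited series values are a single log2 ratio of red over green per probe and array. Its normalization is not given in the sources used here. Its scale and direction were settled against the scanner files. Over the kept probes (defined below) brighter than their median, each column had a correlation of 0.998 to 0.999 with the ratios computed here. The slope of the principal axis was 0.996 to 1.00. Dimmer probes were not compared.

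The main values were computed from mean and background intensities with limma 3.58.1 in R 4.3.3 (data.table version 1.17.8). Background was corrected by normexp with an offset of 50, and each array was normalized by loess with control spots at weight 0. Spots marked as outliers by Feature Extraction were set to missing. The sign was turned so that positive values are higher in the RNA labelled mutant. The 2 dye orientations of a replicate were averaged, so n is 4, and a value needs both orientations. Each array holds 39102 spots, 1417 of them controls, and 37478 other probes. Of these, 25412 were assigned to 1 locus (24875 through a RefSeq accession and 537 through the locus name in the files), 234 to several and 11832 to none. Positions are those of the files (TAIR10). The reference table gave gene names only, and 99.4% of 25411 probe positions lay inside the reference gene. Probes were kept if well above background in the same genotype on at least 4 of its 8 channels, and a gene was represented by its kept probe with the highest mean intensity. This left 21938 probes and 19071 genes, 19034 of them with a fitted value, 18778 with a value in all 4 replicates. Among 484 genes with more than 1 kept probe, 147 had at least 1 probe past the test. All probes were called the same way in 57 of these, some were called and others not in 89, and calls were opposite in 2, where 1 gene counts under both of the last groups.

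Genes were tested with lmFit and eBayes against a log2 ratio of 0, with Benjamini-Hochberg adjustment and an adjusted p threshold of 0.05. The SD given is that between the 4 replicates, with a median of 0.267 over genes. The script was tested on simulated data of 19071 genes with that spread and 200 changed genes. It called 49.3% of the genes changed 1.5-fold, 98.5% of those changed 2-fold and 100% of those changed 3-fold, and 2.37% of its calls were unchanged genes. Fitted over simulated log2 ratios had medians of 0.937, 0.869 and 0.926 at these sizes. Every simulated gene had the same spread and no replicate stood apart, unlike in the real data. The simulated rates therefore check the script and need not hold for the real genes. A dye effect, which the mean of both orientations cancels, was called by limma in 194 genes with the replicate as block (3960 at unadjusted p), in 0 without the block, and in 0 from the differences between the orientations of each replicate (3977 at unadjusted p). The block and difference fits were added after the results were seen.

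Gene lists were fixed by symbol and locus before the data were examined, as were the comparison, the test, the rule for named genes and the alternatives. There were 37 lists with 728 members, of which 718 matched the reference names and 10 were left out. They cover the target genes, their NPY and AGC kinase relatives, auxin, shoot and root development, photosynthesis, epidermis, seed reserves, hormones, nutrients and stress. The 36 lists with at least 5 members were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Beside it camera with an estimated correlation and fry were run. With the estimate, camera uses the few residual degrees of freedom of 4 replicates, so its power was low whatever the correlation. Glucosinolates, with an estimated correlation of -0.0355, still went from a camera adjusted p of 0.083 to 0.537. Failing it therefore does not show that correlation between members accounts for a call. The self-contained test fry asks whether members differ from 0, without comparing them with other genes. These list tests use members with a value in all 4 replicates, while list medians and counts use all members with a value. Called members are counted after adjustment over all genes, and in the closing section after adjustment over the list alone.

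Named genes follow a rule. It names PID and ENP, the 12 largest rises and falls among called genes with the same sign on all 8 arrays, up to 4 called members per list with the largest absolute ratio and the same sign on all arrays, or the member with the smallest p where none was called, and CUC1, CUC2, CUC3, STM, WUS, the NPY relatives, WAG1, WAG2 and PID2 whatever their result. Some of the genes that this rule names are not reported here. For a called gene not well above background in a genotype on any array, a bound on the mean fold is given, without allowance for the spread between replicates.

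Alternatives were the Feature Extraction processed signals, an offset of 16, median centring without loess, scaling between arrays, no filter and a stricter filter on dim probes, the mean of a gene's probes, every probe on its own, all 8 arrays with a dye term and the replicate as block, each slide alone, separate channels, a variance trend with robust fitting, replicate weights, the deposited log2 ratios, each replicate left out, an adjusted p threshold of 0.01, and both other list tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.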

Results

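Messenger RNA of whole Arabidopsis thaliana seedlings was compared between wild type and laterne, a mutant without cotyledons that is homozygous for mutations in both PID and ENP. PID (PINOID) is a protein kinase that acts on PIN auxin efflux carriers, and ENP (ENHANCER OF PINOID, also called NPY1 or MAB4) is an NPH3-like protein that acts with it in cotyledon formation. The labels describe 4 biological replicates, each made of 1 pool of mutant and 1 pool of wild-type seedlings on the 6th day. Each couple of pools was hybridised to 2 two-colour Agilent arrays with the dyes exchanged, which gave 8 arrays. On slide 1 the RNA labelled mutant carried Cy3 on all 4 arrays, and on slide 2 it carried Cy5, so slide and dye orientation cannot be told apart. Between 51.4% and 60.8% of the probes lay well above background per channel. The median probe signal per channel was 73.6 to 162 intensity units over the 8 arrays, against median backgrounds of 32.5 to 59 units, and no spot was saturated. The lowest medians were those of wild type on slide 2 in replicates 2 and 3 (73.6 and 73.7). The 4 biological replicates, rather than the 8 arrays, limit the precision of every value below.

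The comparison asks how gene expression differs between seedlings that form cotyledons and seedlings that do not. All directions follow the dyes given in the labels, as log2 of the RNA labelled mutant over the RNA labelled wild type. Of the mutated genes, ENP went against a loss in the mutant. Its probe gave a higher signal in the RNA labelled mutant, by 1.26 ± 0.37 on the log2 scale (SD, n = 4; limma adjusted p = 0.00433), with 0.76, 1.32, 1.65 and 1.31 in replicates 1 to 4. The PID probe gave -0.19 ± 0.50 (SD, n = 4; limma adjusted p = 0.527), with 0.55 in replicate 1 and -0.46, -0.33 and -0.52 in the others, and it passed the test when replicate 1 was left out (-0.44, limma adjusted p = 0.0203). The ENP probe lies on chromosome 4 from 15390751 to 15390810 and the PID probe on chromosome 2 from 14589959 to 14590018 (TAIR10). The position and kind of the mutations are not given in the sources used here, so either probe may lie outside the altered part and then checks nothing. For this reason the channels are called by their labels throughout, and an exchange of the genotype labels would turn every sign.

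Genes of photosynthesis and photorespiration were the most coherent group, with list medians higher in the RNA labelled mutant in all 4 replicates. In the shoot meristem and organ boundary list, 11 of 20 genes were called lower and 1 higher. The median log2 ratio was 2.1 for photosystem and light-harvesting genes, 2.30 for the Calvin-Benson cycle, 2.42 for photorespiration and 1.52 for chlorophyll synthesis, against -0.52 for the shoot meristem and boundary. The lists of stomata and early auxin response also had medians above 0, at 0.94 and 0.60, with 15 of 16 and 14 of 27 members called higher and none lower. None of the lists named so far passed camera with an estimated correlation (adjusted p = 0.537 for each), a setting with little power at 4 replicates. Of 19034 genes with a value, 3963 (20.8%) passed an adjusted p of 0.05 in limma, 2402 higher and 1561 lower in the RNA labelled mutant, and 1240 of them differed at least 2-fold (908 higher and 332 lower). The share of called genes that were higher was 60.6%, and centring on the array median in place of loess moved it to 75.5%. With the genotype labels exchanged these shares would be 39.4% and 24.5%. The count depended on single replicates. It was 6586 without replicate 1, 1546 without replicate 2, 1510 without replicate 3 and 2197 without replicate 4. Processing moved the counts too, to 9629 called genes with replicate weights and to 2160 genes at 2-fold with Feature Extraction processed signals. The weights were 0.224, 2.74, 3.4 and 0.479 for replicates 1 to 4, so the weighted count rested mainly on replicates 2 and 3. Replicate 1 stood apart from the others, with a correlation across genes of 0.487 with their mean, against 0.862, 0.871 and 0.746 for replicates 2 to 4. Genes are not independent replicates.

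**Figure D1:**
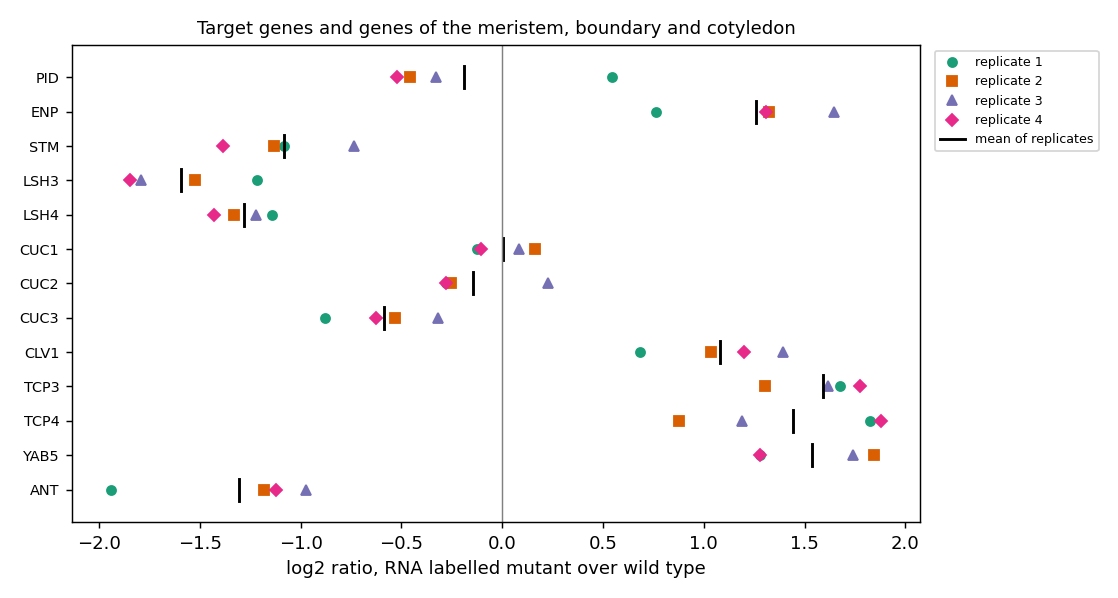
Log2 ratio of the RNA labelled mutant over wild type (horizontal axis) for PID, ENP and genes of the meristem, organ boundary and cotyledon, with 1 point per biological replicate (mean of 2 dye-swapped arrays) and a black bar at the mean of 4. ENP, CLV1, TCP3, TCP4 and YAB5 lie above 0 and STM, LSH3, LSH4, CUC3 and ANT below 0 in every replicate, while PID lies at 0.55 in replicate 1 and between -0.52 and -0.33 in the others.

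All 29 photosystem and light-harvesting genes with a value rose (camera adjusted p = 6.77e-10 on the 13 with a value in all 4 replicates, or adjusted p = 0.537 with an estimated correlation). The photosystem I subunit gene PSAD-2 (2.72 ± 0.74), the light-harvesting gene CAB1 (2.25 ± 0.67), PSAE-1 (2.1 ± 0.58) and the chloroplast ATP synthase gene ATPD (1.91 ± 0.61; each SD, n = 4) were higher on all 8 arrays. All 14 measured Calvin-Benson genes rose too (camera adjusted p = 1.16e-07 on 10 of them, or adjusted p = 0.537 with an estimated correlation). CA1, the chloroplast carbonic anhydrase, a member of the list but not an enzyme of the cycle itself, led them with 4.41 ± 1.20. HCEF1, a fructose bisphosphatase, reached 2.59 ± 0.50, and PRK, phosphoribulokinase, 2.42 ± 0.93. All 8 photorespiration genes rose (camera adjusted p = 5.46e-06 on 6 of them, or adjusted p = 0.537 with an estimated correlation), among them the glycine decarboxylase gene GLDP1 (2.50 ± 0.37), the serine hydroxymethyltransferase gene SHM1 (2.50 ± 0.97) and the glycolate oxidase gene GOX1 (2.41 ± 0.28). In chlorophyll synthesis, 15 of 16 genes rose (camera adjusted p = 7.95e-10 on the 15 members with a value in all 4 replicates, or adjusted p = 0.537 with an estimated correlation), with PORA, which reduces protochlorophyllide, at 3.3 ± 0.61, GUN5 at 1.90 ± 0.55, GUN4 at 1.90 ± 0.26 and CHLM at 1.85 ± 0.21. These 4 list medians were smaller in replicate 1 (1.26, 1.05, 1.22 and 0.74) than in any other replicate. Bright spots of slide 1 were marked as outliers by the scanner software, so that the mean of both dye orientations could not be formed. This left 37 genes without a value, 10 of the photosystem list, 5 of the Calvin-Benson list and 1 of photorespiration among them. With these spots kept, an alternative chosen after seeing the data, 39 of 39, 19 of 19 and 9 of 9 members of these lists rose.

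Stomatal genes rose nearly as a whole, 15 of 16 (camera adjusted p = 1.8e-09, or adjusted p = 0.537 with an estimated correlation). The receptor-like gene TMM, which spaces stomata, rose by 2.48 ± 0.32 and FMA (FAMA), which drives guard cell differentiation, by 2.35 ± 0.40, although FMA was well above background in the wild-type channel on only 2 of 8 arrays. The guard cell regulator MYB60 (1.98 ± 0.62) and the stomatal peptide gene STOMAGEN (1.74 ± 0.32) rose as well. Cutin and wax genes went both ways, with 4 higher and 2 lower of 18 (camera adjusted p = 0.17): the wax genes KCS6 (1.12 ± 0.19) and LACS1 (1.32 ± 0.47) rose, and CER1, needed for wax alkanes, fell by 2.27 ± 0.60, as did PEL3 (-1.52 ± 0.41). In the list of epidermal cell fate, ATML1 rose (0.53 ± 0.15) and the trichome and root hair regulators ETC1 (-1.54 ± 0.43), MYB0 (GL1, -0.88 ± 0.50) and CPC (-0.79 ± 0.36) fell, with MYB0 well above background in the mutant channel on 2 of 8 arrays.

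The 11 genes that fell in the shoot meristem and boundary list, of 20 measured (camera adjusted p = 1.7e-05, or adjusted p = 0.537 with an estimated correlation), included STM, which maintains the shoot meristem (-1.08 ± 0.27), the boundary genes LSH3 (-1.60 ± 0.29) and LSH4 (-1.28 ± 0.13), and CUC3 (-0.59 ± 0.23), a NAC gene of the cotyledon boundary (each SD, n = 4). Its relatives CUC1 (0.00 ± 0.14; limma adjusted p = 0.988) and CUC2 (-0.15 ± 0.25; limma adjusted p = 0.449) did not pass the test. The receptor kinase gene CLV1 was the single member that rose, by 1.08 ± 0.30. WUS had no probe that passed the background filter, so it has no value. Among 25 genes of leaf and cotyledon patterning, 9 rose and 3 fell (camera adjusted p = 0.211). The growth regulators TCP3 (1.59 ± 0.20) and TCP4 (1.44 ± 0.49) and the abaxial gene YAB5 (1.54 ± 0.30) rose, and ANT, which promotes organ growth, fell by 1.31 ± 0.43. Cell cycle genes lay slightly lower as a list, with a median of -0.22 and 3 of 28 past the test, all lower (camera adjusted p = 0.000836, or adjusted p = 0.538 with an estimated correlation). They were the ribonucleotide reductase gene TSO2 (-0.77 ± 0.15), CDKB1;1 (-0.69 ± 0.33) and the cyclin gene CYC1BAT (-0.55 ± 0.33). The cell cycle median was -0.41, -0.10, -0.03 and -0.45 in replicates 1 to 4, and the share of members called lay below the 20.8% of all genes.

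**Figure D2:**
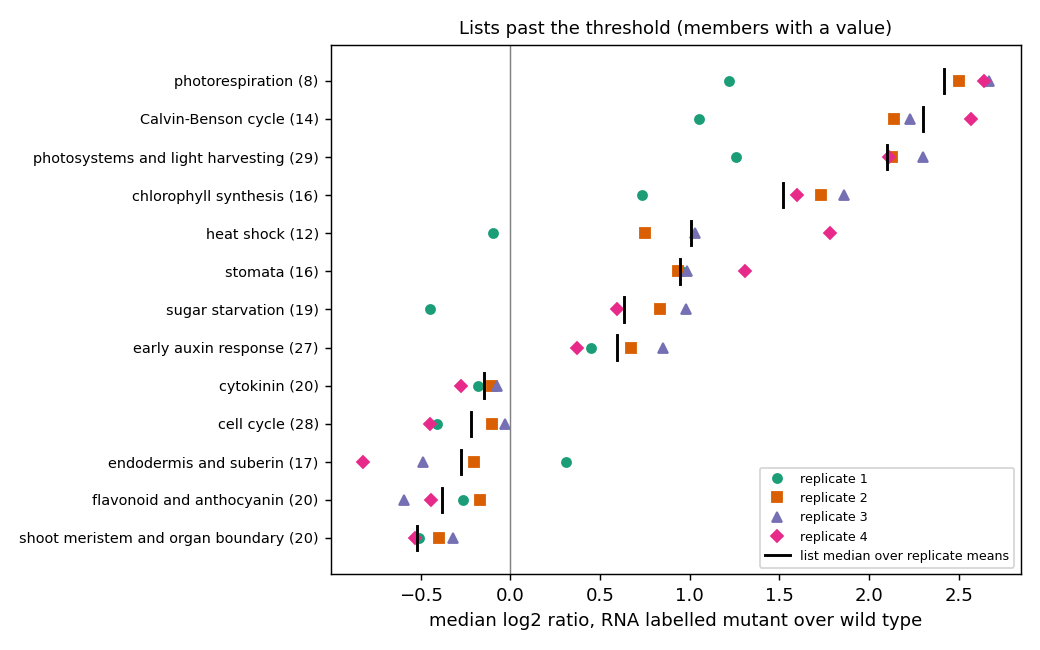
Median log2 ratio of the RNA labelled mutant over wild type (horizontal axis) for the 13 gene lists past an adjusted p of 0.05 in camera with a preset correlation, with 1 point per replicate and a black bar at the list's median over the replicate means. The 4 lists of photosynthesis, photorespiration and chlorophyll have medians of 1.52 to 2.42, with replicate 1 lowest in each, and shoot meristem and organ boundary has -0.52. None of the 13 passes with an estimated correlation, a setting with little power at 4 replicates.

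Auxin genes were called in several groups, against 20.8% called over all genes. The carriers and the relatives of ENP and PID had called shares not far above that. Of 27 early auxin response genes, 14 rose and none fell (camera adjusted p = 8.15e-06, or adjusted p = 0.537 with an estimated correlation). IAA29 rose by 2.23 ± 0.19, IAA20 by 1.47 ± 0.60, the auxin-conjugating enzyme gene BRU6 (GH3.2) by 1.40 ± 0.73 and HAT2 by 1.19 ± 0.40 (each SD, n = 4). IAA29 was well above background in the wild-type channel on 5 of 8 arrays. Among 15 auxin carriers, the influx carriers LAX1 (1.08 ± 0.12) and AUX1 (0.68 ± 0.20) and the efflux carriers PIN3 (0.74 ± 0.09) and PIN4 (0.88 ± 0.21) rose and none fell (camera adjusted p = 0.511). Among 17 genes of auxin synthesis, 5 rose and 3 fell (camera adjusted p = 0.295), with YUC5 (1.54 ± 0.15) and YUC2 (1.52 ± 0.27) higher and the nitrilase gene NIT2 lower (-2.14 ± 0.68). Of 16 genes of auxin perception and response factors, 7 fell and 2 rose (camera adjusted p = 0.129). MP (MONOPTEROS), required for embryonic patterning, fell by 0.77 ± 0.35, ARF17 by 0.91 ± 0.59 and ARF6 by 0.68 ± 0.29, and ARF2 rose by 0.77 ± 0.25. Among the relatives of ENP and PID, NPY3 (0.69 ± 0.15), PID2 (0.45 ± 0.11) and the blue light receptor gene PHOT2 (1.55 ± 0.49) rose and NPY4 fell (-0.61 ± 0.30), while NPY2 (0.13 ± 0.19), NPY5 (0.46 ± 0.34), WAG1 (0.06 ± 0.42) and WAG2 (-0.07 ± 0.75) did not pass (limma adjusted p of 0.464, 0.0757, 0.836 and 0.887). This list of 14 did not pass camera as a whole (adjusted p = 0.175) but passed fry (adjusted p = 0.0428), which does not compare a list with other genes.

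Part of the anthocyanin genes fell. Of 20 flavonoid and anthocyanin genes, 9 fell and none rose (camera adjusted p = 0.00218, or adjusted p = 0.537 with an estimated correlation), and the largest falls among those with the same sign on all 8 arrays were GSTF12 (TT19) at -1.70 ± 0.33, LDOX at -1.54 ± 0.45, DFR at -1.42 ± 0.57 and TT7 at -0.85 ± 0.31 (SD, n = 4). Cytokinin genes lay lower, with 5 of 20 fallen and 1 risen (camera adjusted p = 0.0385, or adjusted p = 0.537 with an estimated correlation). The response regulators RR5 (ARR5, -1.37 ± 0.45) and ARR6 (-1.14 ± 0.23) and the cytokinin hydroxylase gene CYP735A2 (-1.37 ± 0.33; above background in the mutant channel on 4 of 8 arrays) fell, and the cytokinin oxidase gene CKX6 rose (0.95 ± 0.26). This list lost its call without replicate 1 (adjusted p = 0.0551) and without replicate 4 (adjusted p = 0.0815). Sugar starvation genes rose in 7 of 19 cases (camera adjusted p = 0.0374, or adjusted p = 0.632 with an estimated correlation). ASN1, an asparagine synthetase induced in the dark, had the largest rise of all genes that rose on every array (4.84 ± 0.59), and SEN1 (1.64 ± 0.92), TPS11 (1.57 ± 0.67) and ERD5 (1.22 ± 0.42), which degrades proline, followed. The list's median was -0.45 in replicate 1 and 0.84, 0.98 and 0.60 in the others, and its call was lost without replicate 3 (adjusted p = 0.0686). Of 12 heat shock genes, HSP90.1 (1.49 ± 0.31), HSP70 (1.45 ± 0.42) and HSP101 (1.3 ± 0.67) rose (camera adjusted p = 0.0228, or adjusted p = 0.537 with an estimated correlation). This list's call was lost without replicate 4 (adjusted p = 0.121), where its median was 1.78. As a share, its called members lay near the 20.8% of all genes.

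Root lists moved less than the photosynthesis lists. The median was -0.17 for root hair genes (camera adjusted p = 0.0538), -0.28 for endodermis and suberin genes (camera adjusted p = 0.00846, or adjusted p = 0.548 with an estimated correlation) and -0.17 for root identity and transport genes (camera adjusted p = 0.211). Each of these medians was above 0 in replicate 1 (0.23, 0.31 and 0.02) and below 0 in replicates 2 to 4. Called members were 1 of 15 root hair, 2 of 17 endodermis and suberin and 2 of 16 root identity and transport genes, all lower. These shares lay below the 20.8% called over all genes. The regulators RSL4 of root hair growth (-0.80 ± 0.19), MYB36 of the Casparian strip (-0.91 ± 0.29) and WOX5 of the root stem cell niche (-1.51 ± 0.63) were among these members. Without replicate 1 the root hair list passed (median -0.34, adjusted p = 0.0022), and the endodermis median was -0.44. The endodermis call was lost without replicate 4 (median -0.16, adjusted p = 0.0993). No gene of 21 in the seed maturation list passed the test, and the smallest adjusted p was that of the seed regulator ABI3 (0.84 ± 0.80; limma adjusted p = 0.0908). Its median was -0.52, -0.28 and 0.46 in replicates 1 to 3 and 4.21 in replicate 4, the replicate with the highest heat shock and stomatal medians too. The storage protein gene CRA1 lay at 6.15 in replicate 4 and between 0.11 and 1.26 in the others.

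**Figure D3:**
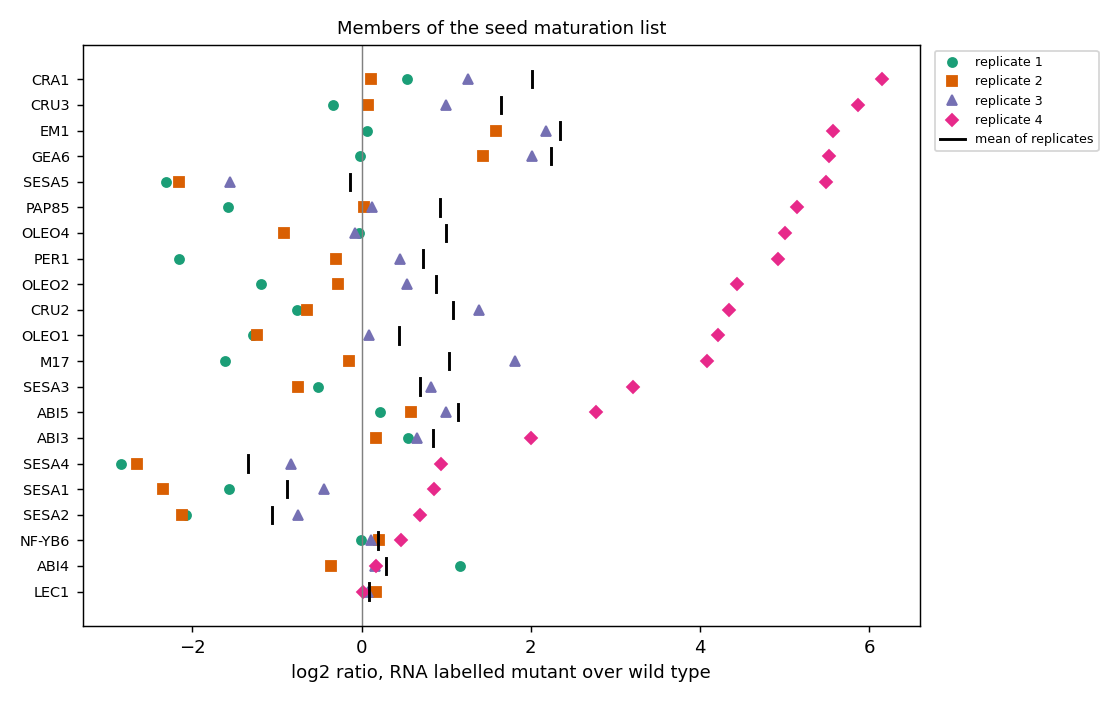
Log2 ratio of the RNA labelled mutant over wild type (horizontal axis) for the 21 measured genes of the seed maturation list, with 1 point per replicate and a black bar at the mean of 4. Replicate 4 lies at 4.08 or above for 12 genes, from CRA1 (6.15) to M17 (4.08), far from the other replicates.

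**Figure D4:**
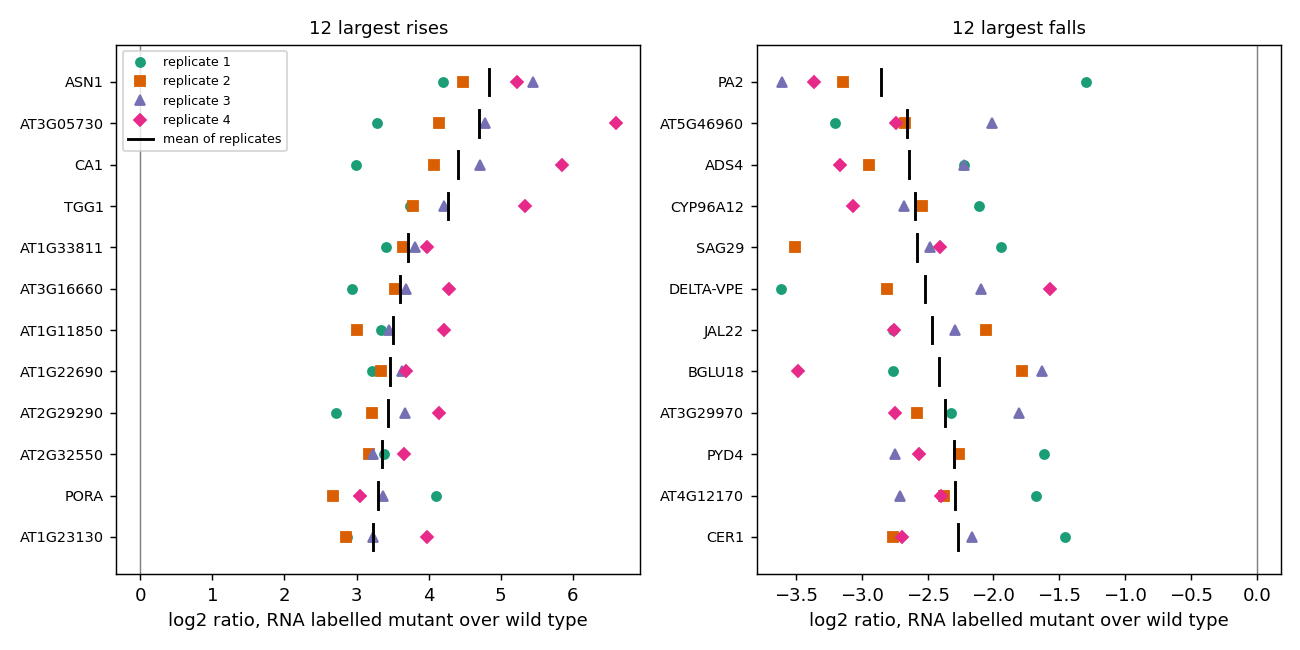
Log2 ratio of the RNA labelled mutant over wild type (horizontal axis) for the 12 largest rises (left) and the 12 largest falls (right) among genes past the limma test with the same sign on all 8 arrays, with 1 point per replicate and a black bar at the mean of 4. The rises have means from 3.23 to 4.84 and the falls from -2.85 to -2.27, and for BGLU18, which was not well above background in the RNA labelled mutant, the plotted value is the fitted ratio.

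The largest single changes included genes of other functions. After ASN1 (AT3G47340), AT3G05730 (4.70 ± 1.41) and CA1 (AT3G01500), the myrosinase gene TGG1 (AT5G26000), which cleaves glucosinolates, rose by 4.27 ± 0.74. Glucosinolate genes as a list did not pass camera (adjusted p = 0.083) but passed fry (adjusted p = 0.00814), which does not compare a list with other genes. AT1G33811 (3.71 ± 0.24), AT3G16660 (3.61 ± 0.55), AT1G11850 (3.5 ± 0.51), AT1G22690 (3.47 ± 0.23), AT2G29290 (3.44 ± 0.61), AT2G32550 (3.36 ± 0.22) and AT1G23130 (3.23 ± 0.53) completed the 12 largest rises with PORA (AT5G54190), a ranking without the 37 genes that had no value. Among these, the light-harvesting gene LHB1B1, chosen after its values were seen, reached 3.67 ± 0.54 (SD, n = 4) with outlier spots kept. The largest fall was that of the peroxidase gene PA2 (AT5G06720; -2.85 ± 1.06), followed by AT5G46960 (-2.66 ± 0.49), the fatty acid desaturase gene ADS4 (-2.64 ± 0.49), the cytochrome P450 gene CYP96A12 (-2.60 ± 0.39), the sugar transporter gene SAG29 (-2.58 ± 0.66) and the vacuolar processing enzyme gene DELTA-VPE (-2.52 ± 0.89; each SD, n = 4). JAL22, a jacalin lectin gene (-2.47 ± 0.35), AT3G29970 (-2.36 ± 0.41), PYD4 (-2.30 ± 0.50), AT4G12170 (-2.29 ± 0.43) and CER1 came next. The beta-glucosidase gene BGLU18 (AT1G52400) was well above background in the wild-type channel on 8 of 8 arrays and in the mutant channel on none. Its mean level was at least 5.15-fold lower in the RNA labelled mutant, a bound that leaves out the spread between replicates. The fitted log2 ratios were -2.76, -1.78, -1.63 and -3.48 in replicates 1 to 4 (limma adjusted p = 0.00499).

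The remaining lists did not pass camera as a whole, although some members were called. In ethylene genes (17 measured, 6 higher and 1 lower; camera adjusted p = 0.0538), the ethylene-forming enzyme gene EFE (2.23 ± 0.29) and the synthase genes ACS11 (1.33 ± 0.31) and ACS6 (1.23 ± 0.56) rose and ACO1 fell (-1.54 ± 0.71). In gibberellin genes (22 measured, 3 higher and 2 lower; camera adjusted p = 0.793), GASA6 rose (2.31 ± 0.71) and the synthesis gene GA3OX1 fell (-1.03 ± 0.51). In genes of abscisic acid, drought and cold (22 measured, 3 higher and 6 lower; camera adjusted p = 0.295), CBF1 rose (1.85 ± 1.40) and ERD10 (-1.21 ± 0.52) and CYP707A1, which degrades abscisic acid (-1.0 ± 0.37), fell. Light and shade signalling (5 higher and 1 lower of 16; camera adjusted p = 0.175) held rises of ELIP2 (1.26 ± 0.15), PIL6 (PIF5, 1.25 ± 0.44) and the cryptochrome gene CRY1 (1.06 ± 0.39). Vascular genes (4 higher of 21; camera adjusted p = 0.0806) held SUC2, the phloem sucrose carrier (1.06 ± 0.47). The other lists and their called counts were iron deficiency with 5 higher and 2 lower of 14 (camera adjusted p = 0.295), phosphate starvation with 3 higher and 2 lower of 15 (0.295), jasmonate and wounding with 3 higher and 3 lower of 19 (0.907), salicylic acid and defence with 3 higher and 1 lower of 15 (0.114), expansins and XTH with 4 higher and 2 lower of 19 (0.73), circadian clock with 1 higher and 1 lower of 17 (0.17), glucosinolates with 2 higher and 1 lower of 16, epidermal cell fate with 1 higher and 3 lower of 13 (0.175) and seed oil mobilisation with 3 higher of 17 (0.807).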

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

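In some named genes and lists 1 replicate lay far from the other 3 by Dixon's test. This held for 13 of 152 named genes and 3 of 37 lists, and chance alone does this in about 1 in 20 groups. Replicate 1 was the distant one, and lower, in genes of photosynthesis, photorespiration and peroxisomes: HCEF1 (1.851 against 2.779 to 2.951 in the others), PRK (1.03 against 2.783 to 2.988), SHM1 (1.054 against 2.863 to 3.179), ATPD (0.9955 against 2.154 to 2.259) and PMDH2 (1.301 against 2.521 to 2.684). The list median of photorespiration behaved alike (1.22 against 2.5 to 2.67). Replicate 1 also stood apart for JAZ1 (-0.4014 against -0.7326 to -0.6797) and for the gibberellin list (0.25 against -0.094 to -0.0678). Replicate 4 was the distant one for ETC1 (-2.179 against -1.384 to -1.242), EFE (2.665 against 2.084 to 2.104), ACS6 (2.065 against 0.873 to 1.069), FRO2 (2.006 against 0.7798 to 0.9383), YSL1 (1.469 against 0.95 to 1.027) and the stomata list (1.31 against 0.937 to 0.987). GSTF12 stood apart in replicate 2 (-1.207 against -1.918 to -1.831) and CUC2 in replicate 3 (0.2264 against -0.2812 to -0.2545). Outside the named genes, 217 of 2221 probes that match no named gene passed the limma test, 155 higher and 62 lower in the RNA labelled mutant.

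The tests of exchanged genotype labels, of an array defect and of seeds in a pool were chosen after the results were seen. Pooled over members, the median was 1.74 for 6 shoot lists and -0.24 for 3 root lists (95% bootstrap interval over genes -0.349 to -0.161), with 0.129 for the root lists in replicate 1 and -0.252, -0.34 and -0.585 in the others, and the cutin and wax, root hair and root identity lists did not pass camera. With the directions as labelled, a lower share of cotyledon tissue in the mutant does not account for these values. Both lists tested for dye bias kept their sign in both orientations (2 of 2), so dye bias does not account for their medians. An exchange of the genotype labels of both channels on all arrays would fit the shoot median of 1.74 and the rise of ENP, and with the signs turned a lower share of cotyledon tissue would no longer be excluded. This remains a hypothesis, since a true rise of the shoot genes in the mutant was not tested, and PID settles nothing (-0.19, limma adjusted p = 0.527; called lower only without replicate 1 or with replicate weights).

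Seed maturation genes stood out in replicate 4, with a list median of 4.21 against -0.515, -0.275 and 0.455 in replicates 1 to 3. A defect of 1 array cannot give this, since the lower of its 2 array medians was 4.17. Seeds or seedlings at an earlier stage in mutant pool 4 could give such values, and its level lay 2.05 above the mean of the other 7 pools. The other mutant pools lay at 0.0126, 0.461 and 0.045, but the wild-type pools were not alike either, from -1.95 in pool 4 to 0.91 in pool 2. Both pools of replicate 4 thus lay outside the others, and the source of the difference stays open.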

How the results depend on the processing

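No named gene or list past the test changed its direction under any setting. Some that did not pass changed sign: CUC1, WAG1 and WAG2, and the list medians of auxin carriers, expansins, gibberellin, jasmonate, seed oil and seed maturation (0.8446, and -0.005961 without replicate 4). The count of changed genes was 3963. It rose to 9629 with replicate weights, fell to 1506 at an adjusted p of 0.01, ranged from 1510 to 6586 with 1 replicate left out, and stayed within 1.5-fold under every other setting. The count at 2-fold (1240) rose to 2160 with Feature Extraction processed signals. The 13 called lists became 0 with an estimated correlation in camera, where single genes are unaffected (6904 genes at unadjusted p, 3963 adjusted in limma), and ranged from 12 to 15 with 1 replicate left out. The 0 came from a setting with little power at 4 replicates. With fry, 17 lists passed, without the heat shock, sugar starvation, cell cycle and endodermis lists. Lists that passed fry but not camera were glucosinolates, leaf patterning, ethylene, cutin and wax, auxin perception, NPY relatives, iron deficiency, and light and shade signalling. A pass in fry alone does not set a list apart from other genes. Apart from the other list tests, the heat shock list lost its call in 7 settings, cytokinin in 5, sugar starvation in 2, cell cycle in 1 and endodermis in 1, and the ethylene list gained a call in 8 and root hair in 6. The lists of circadian clock, seed maturation, vascular tissue, salicylic acid and leaf patterning gained a call in 1 setting each. PID passed with replicate weights (-0.3659), which rest mainly on replicates 2 and 3, and ranged from -0.4362 to -0.08093 with 1 replicate left out. ENP passed everywhere. The share of changed genes that were higher, 60.6%, was 54.8% with processed signals, 60% with offset 16, 75.5% with median centring (2317 higher and 750 lower), 60.1% with scaling between arrays, 61.6% with no filter, 61% with the strict filter, 60.8% with the mean of probes, 61.5% with every probe, 58.7% with the replicate block, 58.5% on slide 1, 63.1% on slide 2, 62.7% with separate channels, 60.4% with trend and robust, 55.5% with replicate weights, 61.6% with the deposited ratios, 72.2% at 0.01, and 56.9% to 71.9% with 1 replicate left out. With the genotype labels exchanged each share would be 100% less the value given, 39.4% in place of 60.6%. For these differences the cause was not tested, except that a stricter threshold calls fewer genes by construction. Among alternatives chosen after seeing the data, the share was 60.1% without seed genes and genes 4-fold higher in replicate 4, and 60.8% with outlier spots kept. Channels in which 51.4% to 60.8% of the probes lay well above background limit what can be said of weak genes, and 14 called genes were above it on no array of the RNA labelled mutant and 34 on none of wild type.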

Other observations

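Some nutrient and defence genes were called, in both directions within each list, and none of these lists passed camera. Of 14 iron genes 5 rose and 2 fell, and this list passed fry (adjusted p = 0.0428), which does not compare it with other genes. Among iron genes, the ferric reductase gene FRO2 (1.14 ± 0.58) and the transporter gene YSL1 (1.11 ± 0.24) rose, and the nicotianamine synthase genes NAS4 (-1.17 ± 0.38) and NAS1 (-1.05 ± 0.54) fell (each SD, n = 4). The phosphate carrier gene PHT1;1 (-1.17 ± 0.55) and the ribonuclease gene RNS1 (-0.93 ± 0.69) fell, and the lipid genes SQD2 (0.65 ± 0.26) and MGD2 (0.59 ± 0.26) rose. The defence kinase gene FRK1 (1.79 ± 0.87) and WRKY70 (0.56 ± 0.14) rose, and the salicylic acid synthesis gene EDS16 (ICS1) fell (-1.04 ± 0.27). The jasmonate genes TIFY7 (1.34 ± 0.34) and LOX2 (0.98 ± 0.45; well above background in the wild-type channel on 2 of 8 arrays) rose, and AOC4 (-0.83 ± 0.29) and JAZ1 (-0.64 ± 0.16) fell.

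Some cell wall and clock genes were called too. The xyloglucan endotransglucosylase gene TCH4 (1.49 ± 0.43) and the expansin genes EXPA1 (1.35 ± 0.39) and EXPA8 (0.97 ± 0.54) rose, and EXPA2 fell (-1.51 ± 0.72; SD, n = 4). The clock gene RVE8 rose (0.83 ± 0.18) and ELF4 fell (-0.77 ± 0.26). PMDH2, a peroxisomal malate dehydrogenase gene, rose by 2.27 ± 0.65. After adjustment over the list alone in limma, 19 early auxin response genes rose and 2 fell, against 14 and 0 over all genes, 1 meristem and boundary gene rose and 13 fell, against 1 and 11, and 1 flavonoid gene rose and 10 fell, against 0 and 9.

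Chance as the source of the gene counts was tested by regrouping. Of 8 sign patterns of the replicates, only the real one (1) gave as many called genes (3963), and the highest other gave 0, but 8 patterns are too few to put the share under 0.05, so this alone cannot tell. Of 35 splits of the 8 RNA pools into 4 and 4, only the real one (1) gave as many (3267), and the highest other gave 2. These splits used the unpaired fit of separate channels, which ignores that each mutant pool was hybridised with its own wild-type pool.

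A chromosome segment of another line linked to PID or ENP was tested as a source of changed genes. Within 2 Mb of either gene 20.2% of 1688 genes were called, against 20.9% of 17341 elsewhere, an odds ratio of 0.959 (95% confidence interval 0.845 to 1.09; p = 0.771 in a permutation test by circular shifts along the chromosomes), so no excess near either gene was found.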
